A study of Homo sapiens with 18 samples.

How the data were processed

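Gene expression was measured in human T-lymphocytes on 18 Affymetrix whole-genome expression arrays, 1 array per RNA sample. The lymphocytes came from the blood of 2 healthy volunteers, called donor A and donor B here. They were stimulated with 1.5% phytohaemagglutinin (PHA), a plant lectin that drives T cells to divide. After 48 h of PHA they received a drug or the vehicle for a further 24 h, so RNA was taken 72 h after PHA. Doxorubicin, an anthracycline that poisons topoisomerase and damages DNA, was given at 0.3 µg/ml. Nutlin-3, a small molecule that blocks the binding of MDM2 to p53, was given at 10 µM. Control cells received 0.1% DMSO. Per the labels, nutlin-3 was dissolved in DMSO and doxorubicin in water, so the DMSO control matched the vehicle of nutlin-3 and not that of doxorubicin. Each donor supplied 3 arrays for each of the 3 treatments, which made 6 groups. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical, and 2 donors cannot show how people vary.

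The deposited values were signal intensity values per probe set on a linear scale. The submitters' processing notes name MAS5, an Affymetrix method that combines the probes of a probe set into 1 signal and scales each array to a common level; its version and settings were not given in the sources used here. The values themselves showed that scaling: with 2% of the values trimmed at either end, the mean of every array was 500.1. Detection calls were not used here. Array medians on the log2 scale spanned 0.29, under the limit of 0.5 set for any further scaling, so the values were kept as deposited and taken to log2 with no pseudocount. For arrays, precision is limited by the number of arrays and, for dim probe sets, by signal near the background.

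The 54675 probe sets comprised 62 Affymetrix controls, 41091 with 1 gene symbol, 1801 with several symbols and 11721 with no symbol here. Probe sets with 1 symbol covered 19740 genes. A probe set entered the tests if it lay above the median of its array in at least 6 of the 18 arrays, which 29257 probe sets did. Each gene was represented by the probe set with the highest mean log2 signal, which left 12448 genes. Controls, probe sets with no gene or several genes, and Y-linked genes and XIST were left out of the tests. No genome build was given, so no coordinates are stated.

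Each drug was compared with DMSO, and the drugs with each other, in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend over all 18 arrays and with donor as a covariate. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12448 genes. Whether a drug response differed between the donors was tested as an interaction in a fit of the 6 group means. Errors of log2 fold changes are standard errors (SE) from limma, with 6 arrays per treatment, and each named gene's fold is the absolute fold of its log2 value. The overlap of the calls for both drugs, which share their DMSO arrays, was set beside a simulation with no drug effect and beside fits in which each drug had its own 3 DMSO arrays. RNA quality was compared by exact permutation tests on 3' minus 5' signal of the GAPDH and ACTB control probe sets.

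There were 23 gene lists. They covered p53 targets, death receptor and mitochondrial apoptosis, anti-apoptosis, G1/S and replication, G2/M and mitosis, Fanconi and homologous recombination, replication-dependent histones, the APOBEC3 family, Toll-like receptors, NF-kB inflammatory genes and interferon-stimulated genes. They also covered T cell activation, T cell identity, markers of B cells, monocytes, natural killer cells, and platelets and erythroid cells, immediate early genes, the integrated stress response (ATF4 targets), chaperones, ribosome biogenesis, sterol synthesis and glycolysis. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves on balance to 1 side, were run beside it. Members were counted as called over all genes and as adjusted over the list alone. For the lists of the drug comparisons whose counts are stated, the second count is given where it differed. The p53 and apoptosis lists shared 7 measured members, and the p53 and interferon lists shared 1, TRIM22.

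Groups, tests, filter, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Under that rule the text could name, for each drug, the 10 largest rises and the 8 largest falls among called genes that changed at least 2-fold with the same sign in both donors. It could also name up to 3 called members of each list per drug with the largest change (the brightest member where none was called), CDKN1A, MDM2 and FAS, the 8 largest called differences in each direction between the drugs, and the 5 largest called differences between donors. The rule also listed other genes that were not analysed here. Genes of HLA, KIR, immunoglobulin and T cell receptor segments, Y-linked genes, XIST and unofficial symbols were passed over. Some genes under the rule are left out for length. Lists of TNF superfamily genes, cytosolic tRNA synthetases and metallothioneins were chosen after the values were seen, as were the camera tests of differences between donors.

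The fit was tested on simulated data with the spread of these arrays, in 5 simulations of 200 changed genes among 12448 for doxorubicin against DMSO. It recovered 32% of genes changed 1.25-fold, 64% at 1.5-fold, 84% at 2-fold and 96% at 4-fold, and 5.8% of its calls were false. For a difference between donors it recovered 1%, 25%, 53% and 81% at these sizes, and 3.1% of its calls were false.

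Alternatives covered quantile normalization, centring each array on its median, a pseudocount of 16, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets named _x_at or _s_at (which can match several transcripts), 2 other variance moderations, fits of only the arrays compared or of 6 group means, a replicate block, each donor alone, and each of the 18 arrays left out in turn. Replicate numbers did not pair the arrays: after group means were removed, same-numbered pairs correlated across genes with r between -0.04 and 0.04. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.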

Results

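Transcript levels were measured on 18 arrays, 3 for each of 6 groups: donor A and donor B, each with DMSO, doxorubicin or nutlin-3. Each array gave a signal for each of 54675 probe sets, and the median signal of an array lay between 96.8 and 118.1. Replicate arrays of a group correlated with r from 0.960 to 0.969 across the 12448 genes tested, which are not independent replicates. Over these genes their median absolute difference was 0.16 to 0.22 on the log2 scale. The first principal component held 46.2% of the variance and parted the donors. The GAPDH 3' minus 5' signal, a sign of RNA degradation, was 0.71 ± 0.18 (log2, SD, n = 6) with DMSO, 0.72 ± 0.09 with doxorubicin and 0.67 ± 0.14 with nutlin-3. Exact permutation tests gave p = 0.887 for doxorubicin and p = 0.729 for nutlin-3. For ACTB the values were 2.38 ± 0.32, 2.47 ± 0.20 and 2.41 ± 0.36, with exact permutation p = 0.595 and p = 0.890. For every gene under the rule that a drug changed, all 6 arrays of the drug lay on 1 side of their donor's DMSO mean. The exceptions, with 5 of 6 arrays each, were ATF3 and FANCI with doxorubicin and COG8 with nutlin-3. Genes named only from the lists chosen later were not counted this way. GAPDH, a housekeeping gene, had log2 fold changes of 0.01 with doxorubicin and 0.04 with nutlin-3.

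The series asked how p53-dependent transcription responds in dividing T cells, and the comparison of doxorubicin with DMSO addresses DNA damage. Doxorubicin raised known p53 target genes and lowered ATF4 targets, among them genes of serine synthesis. MDM2, which encodes the ubiquitin ligase that degrades p53, rose 2.59-fold (log2 1.37 ± 0.16, SE, 6 arrays per treatment, adjusted p = 6.77e-06). TP53I3, a quinone oxidoreductase gene, rose 5.24-fold (log2 2.39 ± 0.29, adjusted p = 1.15e-05), and BAX, a pro-apoptotic BCL2 family gene, rose 2.30-fold (log2 1.20 ± 0.11, adjusted p = 1.57e-07). PSAT1 and PHGDH, which encode enzymes of serine synthesis, were 2.43-fold and 2.27-fold lower (log2 -1.28 ± 0.14 and -1.18 ± 0.15, adjusted p = 1.67e-06 and 2.42e-05).

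Of 45 measured p53 targets, doxorubicin raised 31 and lowered 0, with 34 up when adjusted over the list alone. Their median log2 fold change was 0.79 (camera adjusted p = 2.90e-57). The cell cycle inhibitor CDKN1A rose 1.77-fold (log2 0.82 ± 0.15, adjusted p = 0.002). The kinase gene PLK2 rose 4.61-fold (log2 2.20 ± 0.34) and the ceramidase gene ACER2 rose 4.91-fold (log2 2.30 ± 0.41), from DMSO signals of 68.4 and 50.2, below the array medians. SPATA18, a gene of mitochondrial quality control, had the largest rise of the genes named for doxorubicin, 11.98-fold (log2 3.58 ± 0.69, adjusted p = 0.003). Its mean DMSO signal of 7.8 lay far below the array medians, so that fold rests on a dim control, and the call ended in a fit of only the arrays compared (adjusted p = 0.096). The GDF15 rise of 2.37 (log2, ± 0.63, adjusted p = 0.044) also started from a dim signal of 12.3 and was lost when any of 13 arrays was left out. FAS, the death receptor gene, rose 1.31-fold (log2 0.39 ± 0.06, adjusted p = 3.44e-04), with adjusted p = 0.464 for its probe set outside the _x_at and _s_at classes.

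Outside the p53 list, the costimulatory ligand gene TNFSF4 (OX40 ligand) rose 4.85-fold (log2 2.28 ± 0.22, adjusted p = 4.66e-07), and TNFSF8 (CD30 ligand) rose 2.12-fold (log2 1.08 ± 0.17). IGFL2, a member of the IGF-like family, rose 6.34-fold (log2 2.66 ± 0.32), and VWCE rose 3.16-fold (log2 1.66 ± 0.21). HES2, a transcriptional repressor gene, rose 3.31-fold (log2 1.73 ± 0.35, adjusted p = 0.005) from a DMSO signal of 67.7. CHAC1, a glutathione-degrading enzyme gene and ATF4 target, was 2.46-fold lower (log2 -1.30 ± 0.22, adjusted p = 7.45e-04).

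The integrated stress response list, which holds ATF4 targets such as PSAT1, PHGDH and CHAC1, had 15 of 23 members down and 0 up (19 down when adjusted over the list alone; median -0.46, camera adjusted p = 1.04e-26). In ribosome biogenesis, 5 of 35 members fell and 0 rose (11 down adjusted over the list alone; median -0.20, adjusted p = 9.66e-09). Among them were the nucleolar genes NOLC1 (-0.55 ± 0.07) and WDR3 (log2 -0.54, adjusted p = 0.002). Of 5 APOBEC3 cytidine deaminases, 2 rose (3 adjusted over the list alone; median 0.33, adjusted p = 7.57e-06). These were APOBEC3B, at 1.73-fold (log2 0.79 ± 0.10), and APOBEC3C, at 1.63-fold (log2 0.70 ± 0.08).

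In the apoptosis list 4 of 22 members rose and 0 fell (7 up and 2 down adjusted over the list alone; median 0.16, adjusted p = 2.57e-05). The 4 were AEN, BAX, FAS and TNFRSF10B, all of which the p53 list also holds. The exonuclease gene AEN rose 2.23-fold and the TRAIL receptor gene TNFRSF10B 2.04-fold, although another probe set of TNFRSF10B stood at -0.20. Of 30 T cell activation genes, 5 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.12, adjusted p = 3.85e-05). They included TNFSF8, the growth factor gene IL2 (log2 0.51 ± 0.09, adjusted p = 0.002) and the cytokine gene IFNG (0.40 ± 0.07, adjusted p = 0.002). NF-kB genes had 1 of 26 up (median 0.08, camera adjusted p = 0.017, and adjusted p = 0.523 with an estimated correlation). Sterol synthesis had 1 of 16 up (2 adjusted over the list alone), the sterol carrier gene STARD4 (log2 0.36, list median 0.09, camera adjusted p = 0.017, and adjusted p = 0.124 with an estimated correlation). With centring on the array median, STARD4 missed the threshold (adjusted p = 0.060).

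For the remaining 15 lists the camera adjusted p lay between 0.083 and 0.743. G1/S and replication genes had 2 up and 1 down of 45 (2 and 2 adjusted over the list alone; median -0.04, adjusted p = 0.519): PCNA, the replication clamp, rose 1.51-fold (log2 0.59 ± 0.06, adjusted p = 4.66e-07), and UNG, a uracil glycosylase gene, was 1.39-fold lower (log2 -0.48 ± 0.10). G2/M genes had 2 up of 53 (3 adjusted over the list alone; median 0.03, adjusted p = 0.286), and the Fanconi and homologous recombination list had 1 up and 1 down of 24 (median 0.05, adjusted p = 0.519). The fallen member was the DNA damage kinase gene ATM (-0.38, adjusted p = 0.010), with adjusted p = 0.772 for the mean of its probe sets. Interferon-stimulated genes had 3 of 41 up (4 adjusted over the list alone, median -0.05, mean 0.01, adjusted p = 0.703), among them TRIM22 at 1.73-fold (log2 0.79 ± 0.08) and HERC5 at 1.66-fold (0.73 ± 0.10). Immediate early genes had 2 up and 2 down of 21 (4 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.083), with EGR1 1.44-fold lower (log2 -0.53 ± 0.09) and IER5 1.34-fold higher (log2 0.43 ± 0.05). Glycolysis had 1 up of 21, the enolase gene ENO2 (log2 0.27, list median 0.04, list adjusted p = 0.083), which lost its call with arrays centred on their medians (adjusted p = 0.099).

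Markers of other blood cells were not called as lists with doxorubicin. Some had DMSO signals far above the array medians, such as MS4A1 (CD20) at 5149.3 and CD14 at 1662.0. The arrays measured the cells of a culture together. For either drug, a change in the share of a cell type therefore cannot be told from a change within cells. B cell markers had 2 of 12 down (median -0.11, adjusted p = 0.083), among them BANK1 (log2 -0.43), and monocyte markers had 1 of 14 down (median -0.09, adjusted p = 0.276), CD14 at 1.68-fold lower (log2 -0.75 ± 0.13). No call was made among 9 natural killer cell markers (median 0.06, adjusted p = 0.703; GNLY at -0.01) or 6 platelet and erythroid markers (1 up adjusted over the list alone, median 0.19, adjusted p = 0.298). T cell identity genes had 0 up and 1 down of 24 (1 and 2 adjusted over the list alone; median 0.01, mean 0.00, test direction down, adjusted p = 0.743). No member was called among 9 anti-apoptosis genes (1 up adjusted over the list alone, median 0.03, adjusted p = 0.290; MCL1 at 0.01), 20 histone genes (median -0.04, adjusted p = 0.641; H1-2 at -0.03), 7 Toll-like receptors (median 0.11, adjusted p = 0.276; TLR2 at 0.11) or 15 chaperones (median 0.08, adjusted p = 0.123; HSP90AA1 at 0.07). Centring on the array median turned the sign of the medians for anti-apoptosis, G2/M and T cell identity.

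Doxorubicin changed 342 of 12448 genes, 192 up and 150 down, of which 32 rose and 4 fell at least 2-fold. Of the 8 lists called, 6 held with an estimated correlation: p53 targets (adjusted p = 9.97e-04), apoptosis (0.036), APOBEC3 (0.002), T cell activation (0.028), the stress response (9.97e-04) and ribosome biogenesis (0.003). The count was 361 in donor A alone and 52 in donor B alone, and it was 205 with arrays centred on their medians and 204 without probe sets named _x_at or _s_at; centring gave 3 ribosome biogenesis genes down and 0 NF-kB, sterol synthesis, glycolysis and G2/M genes up. The control lacked the vehicle of doxorubicin, so the comparison holds the drug and the difference in vehicle together.

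**Figure D1:**
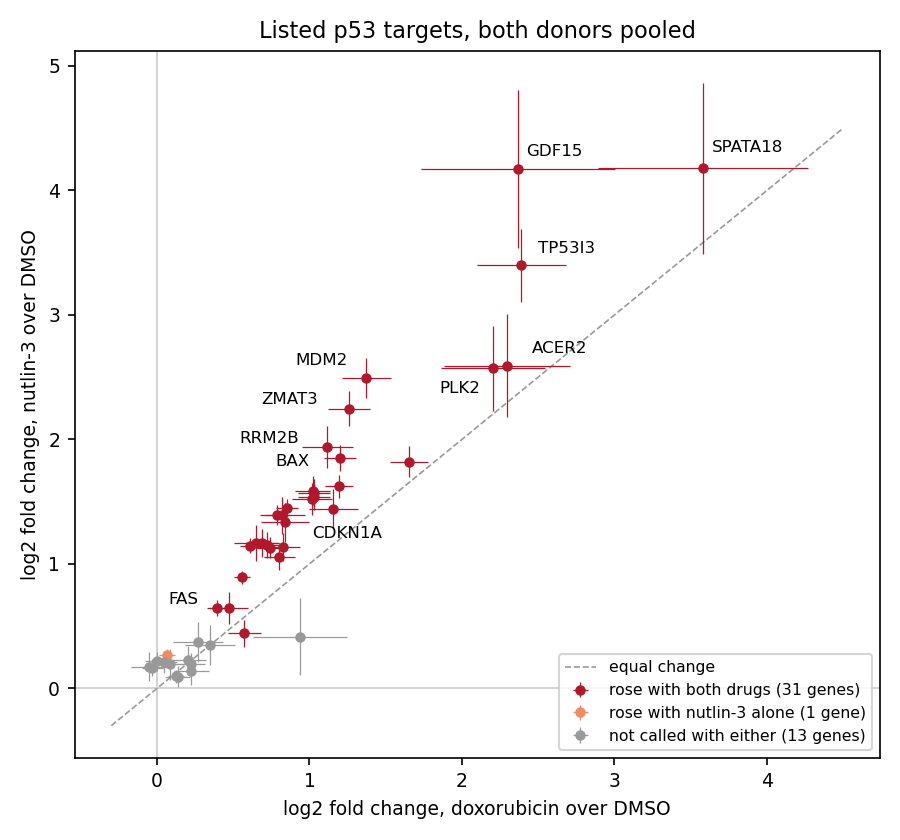
Log2 fold change of each of the 45 measured p53 targets over DMSO, with doxorubicin on the horizontal axis and nutlin-3 on the vertical axis (points, with SE bars from limma, both donors pooled). The 31 genes that rose with both drugs are in red, 1 gene that rose with nutlin-3 alone is in orange and 13 not called with either are in grey, and MDM2 lies above the line of equal change (1.37 and 2.50).

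The comparison of nutlin-3 with DMSO addresses p53 activation without DNA damage, since nutlin-3 frees p53 from MDM2. With the donors pooled, nutlin-3 raised p53 targets further than doxorubicin did, and lowered genes of DNA replication, ATF4 targets and genes of ribosome biogenesis. The median log2 fold changes of the p53 targets with doxorubicin and nutlin-3 were 0.98 and 1.07 in donor A. In donor B they were 0.52 and 1.27, so the gap lay mainly there. MDM2 rose 5.64-fold (log2 2.50 ± 0.16, adjusted p = 1.34e-10), CDKN1A 2.62-fold (log2 1.39, adjusted p = 5.38e-07), BAX 3.61-fold (log2 1.85, adjusted p = 1.38e-11) and TP53I3 10.54-fold (log2 3.40, adjusted p = 1.84e-08). MYC, the proto-oncogene of cell growth, was 1.99-fold lower (log2 -0.99 ± 0.09, adjusted p = 8.85e-08). CYP4F3, a leukotriene hydroxylase gene, rose 23.23-fold (log2 4.54 ± 0.45, adjusted p = 2.11e-07) from a mean DMSO signal of 22.9, far below the array medians, so the size of this fold is uncertain.

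Of the 45 p53 targets 32 rose and 0 fell with nutlin-3 (38 up adjusted over the list alone; median 1.15, camera adjusted p = 1.72e-76). SPATA18 rose 18.09-fold (log2 4.18 ± 0.69), and GDF15, a stress-induced cytokine gene, rose 18.05-fold (log2 4.17, adjusted p = 1.13e-04); with DMSO signals of 7.8 and 12.3, the size of these folds is uncertain. ZMAT3, which encodes a p53-induced RNA-binding protein, rose 4.75-fold, and RRM2B, the p53-inducible ribonucleotide reductase subunit, rose 3.83-fold. FAS rose 1.56-fold (log2 0.65, adjusted p = 1.19e-07), again with no call outside the _x_at and _s_at probe sets (adjusted p = 0.454). In the apoptosis list 4 of 22 rose (median 0.09, adjusted p = 1.79e-05), with TNFRSF10B at 2.91-fold and AEN at 2.72-fold. Of 9 anti-apoptosis genes 1 rose (median 0.05, adjusted p = 0.411), BCL2L1, at 1.45-fold; with the mean of its probe sets its adjusted p was 0.144. TNFSF4 rose 6.55-fold and TNFSF8 2.71-fold.

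G1/S and replication genes had 24 of 45 down and 1 up with nutlin-3 (31 down and 1 up adjusted over the list alone; median -0.35, camera adjusted p = 1.85e-23). The exception was PCNA, which rose 1.27-fold (log2 0.34, adjusted p = 3.39e-04). UNG was 1.62-fold lower (log2 -0.69) and the transcription factor gene E2F8 1.56-fold lower (log2 -0.65 ± 0.13). G2/M genes had 6 of 53 down (11 adjusted over the list alone, median -0.16). Their camera adjusted p was 8.18e-10, and adjusted p = 0.188 with an estimated correlation. Among the 6 were MYBL2, a cell cycle transcription factor gene, 1.48-fold lower (log2 -0.56), and the spindle checkpoint kinase gene BUB1B (-0.45, adjusted p = 0.004). The Fanconi and homologous recombination list had 4 of 24 down (9 adjusted over the list alone; median -0.14, adjusted p = 2.68e-05), including the recombination gene RAD54L (-0.59) and the exonuclease gene EXO1 (-0.43). Among 20 histone genes none was called (median -0.11, adjusted p = 0.235; H1-2 at -0.11).

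The stress response list had 16 of 23 members down and 0 up (19 down adjusted over the list alone; median -0.40, adjusted p = 1.95e-22). PHGDH was 2.35-fold lower (log2 -1.23, adjusted p = 6.54e-06), PSAT1 2.33-fold lower (log2 -1.22) and CHAC1 2.14-fold lower (log2 -1.10). Ribosome biogenesis had 13 of 35 down and 0 up (19 adjusted over the list alone; median -0.30, adjusted p = 1.05e-13), with NOLC1 1.58-fold lower (log2 -0.66, adjusted p = 8.33e-07), NOP16 1.55-fold lower (log2 -0.63) and BYSL 1.54-fold lower (log2 -0.62). The urea cycle gene ASS1 (-1.20 ± 0.21), the phospholipid methyltransferase gene PEMT (-1.58 ± 0.39) and the folate carrier gene SLC19A1 (-1.14 ± 0.22) fell more than 2-fold with the donors pooled. The log2 values in donor A and donor B were -0.47 and -2.68 for PEMT, which was not called in either donor alone and had a nutlin-3 signal of 62.7, below the array medians, and -0.80 and -1.48 for SLC19A1. SLC19A1 lost its call without _x_at and _s_at probe sets (adjusted p = 0.563). Sterol synthesis had 4 of 16 up (5 adjusted over the list alone; median 0.20, adjusted p = 2.92e-06): STARD4 rose 1.51-fold (log2 0.60 ± 0.07), and MSMO1 and HMGCS1, enzymes of the pathway, 1.34-fold and 1.32-fold. APOBEC3 genes had 3 of 5 up (median 0.46, adjusted p = 1.79e-05), with APOBEC3C at 1.76-fold and APOBEC3B at 1.37-fold. The third, APOBEC3G (log2 0.43, adjusted p = 0.006), had a mean of its probe sets of -0.17 (adjusted p = 0.719).

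With nutlin-3, T cell identity had 4 of 24 up (5 adjusted over the list alone; median 0.11, camera adjusted p = 8.38e-04, and adjusted p = 0.188 with an estimated correlation), with the homing receptor gene CCR7 at 1.46-fold and the adhesion receptor gene CD2 at 1.32-fold. T cell activation had 3 up and 2 down of 30 (8 and 4 adjusted over the list alone; median 0.11, camera adjusted p = 0.018, and adjusted p = 0.188 with an estimated correlation); TNFSF8 and IFNG (log2 0.54) rose and MYC fell. NF-kB genes had 2 of 26 up (median 0.12, camera adjusted p = 0.002, and adjusted p = 0.298 with an estimated correlation), among them EBI3, a cytokine subunit gene, at 1.50-fold. Immediate early genes had 3 of 21 up (median 0.12, camera adjusted p = 0.007, and adjusted p = 0.214 with an estimated correlation), among them IER5 at 1.61-fold, NR4A3 (log2 0.44) and ATF3 (log2 0.32); with the mean of their probe sets NR4A3 (adjusted p = 0.347) and ATF3 (adjusted p = 0.794) were not called. Interferon-stimulated genes had 3 up and 1 down of 41 (3 and 2 adjusted over the list alone; median 0.06, adjusted p = 0.090): TRIM22 rose 2.62-fold and HERC5 1.69-fold, and the exonuclease gene ISG20 was 1.53-fold lower (log2 -0.62 ± 0.10).

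B cell markers had 2 up and 1 down of 12 (2 and 2 adjusted over the list alone; median 0.04, mean -0.03, test direction up, adjusted p = 0.614): MS4A1 (CD20) rose 1.28-fold and the complement receptor gene CR2 was 1.76-fold lower (log2 -0.82). Monocyte markers had 1 of 14 up and 0 down (1 and 2 adjusted over the list alone; median -0.11, adjusted p = 0.614; CD14 at -0.21). No call was made among 9 natural killer cell markers (median -0.07, adjusted p = 0.551; GNLY at -0.13), 6 platelet and erythroid markers (median -0.17, adjusted p = 0.518), 7 Toll-like receptors (median 0.08, adjusted p = 0.574), 15 chaperones (median -0.02, adjusted p = 0.235) or 21 glycolysis genes (median -0.02, adjusted p = 0.260).

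Nutlin-3 changed 656 of 12448 genes, 359 up and 297 down, of which 59 rose and 10 fell at least 2-fold. Of the 13 lists called, 8 held with an estimated correlation: p53 targets (adjusted p = 2.45e-04), apoptosis (0.027), G1/S (0.007), Fanconi and homologous recombination (0.006), APOBEC3 (0.002), the stress response (0.002), ribosome biogenesis (6.24e-04) and sterol synthesis (0.005). The count was 210 in donor A alone and 323 in donor B alone. It was 397 with arrays centred on their medians, where the upward share of calls went from 54.7% to 67.3%, and 404 without _x_at and _s_at probe sets. Centring also gave 2 G2/M and 7 ribosome biogenesis genes down, 2 T cell identity genes and 1 NF-kB gene up, and 0 monocyte markers called.

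**Figure D2:**
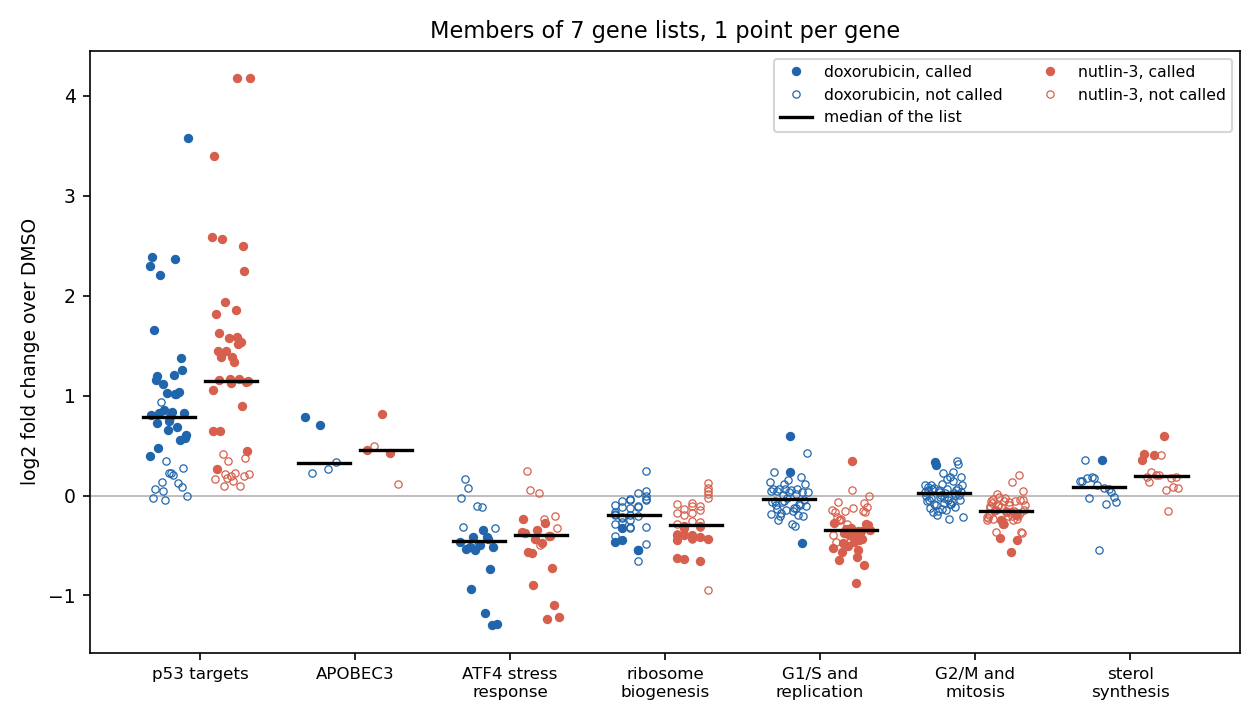
Log2 fold change over DMSO (vertical axis) of each measured member of 7 gene lists with doxorubicin (blue) and nutlin-3 (red); filled points were called, open points were not, and bars are list medians. The p53 list has medians of 0.79 and 1.15, and the G1/S list -0.04 and -0.35; the small G2/M median for doxorubicin (0.03) turned to -0.01 with arrays centred on their medians.

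The direct contrast of the drugs asks which genes differed between doxorubicin at 0.3 µg/ml and nutlin-3 at 10 µM, both after 24 h. No measure of DNA damage or of p53 protein was available here to match the doses. Effects of dose or timing therefore cannot be told from a difference between DNA damage and release of p53 from MDM2. The drugs also differed in vehicle (water and DMSO), which this contrast cannot part from the drugs. With the donors pooled, the p53 targets were lower with doxorubicin than with nutlin-3, and the replication genes were higher. The list medians of both differences were larger in donor B (below). MDM2 was 2.18-fold lower with doxorubicin than with nutlin-3 (log2 -1.12 ± 0.16, adjusted p = 3.77e-04, lower in 6 of 6 doxorubicin arrays than the mean of the donor's nutlin-3 arrays), and ZMAT3 1.99-fold lower (log2 -0.99, adjusted p = 3.14e-04). BAX (-0.65, adjusted p = 0.001), TNFRSF10B (-0.51), RRM2B (-0.82) and CDKN1A (-0.57, adjusted p = 0.046) differed the same way, each in 6 of 6 arrays. The CDKN1A call was lost when any of 12 arrays was left out, and variance moderation without a trend ended it (adjusted p = 0.142) and those of RRM2B (0.062) and TNFRSF10B (0.060); the mean of its probe sets also ended that of TNFRSF10B (0.415). E2F8 (0.69, adjusted p = 0.005) and MYC (0.61, adjusted p = 7.01e-04) were higher with doxorubicin, each in 6 of 6 arrays.

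In the p53 list, 18 of 45 members were lower with doxorubicin and 0 higher (27 lower adjusted over the list alone; median -0.34, camera adjusted p = 4.39e-22). The median was -0.14 in donor A and -0.67 in donor B. G1/S genes had 15 of 45 higher and 0 lower (35 higher adjusted over the list alone; median 0.29, 0.14 in donor A and 0.40 in donor B, adjusted p = 1.21e-28), among them PCNA (0.25, adjusted p = 0.022). The PCNA call was lost with arrays centred on their medians (adjusted p = 0.263), with no variance trend (0.075), and without doxorubicin replicate 2 or nutlin-3 replicate 2 of donor B (0.054 for each). G2/M genes had 7 of 53 higher (20 adjusted over the list alone; median 0.20, camera adjusted p = 1.08e-16, and adjusted p = 0.124 with an estimated correlation), and the Fanconi and homologous recombination list had 6 of 24 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.23, adjusted p = 7.03e-08). EXO1 (0.39, adjusted p = 0.036) was among those higher, but lost its call when any of 7 arrays was left out. ATM (-0.45, adjusted p = 0.004) was the lower member, with adjusted p = 0.813 for the mean of its probe sets. With arrays centred on their medians the counts of higher genes were 5 for G1/S, 1 for G2/M and 0 for the Fanconi list, and 2 T cell identity genes were lower. T cell identity genes had 5 of 24 lower (8 adjusted over the list alone; median -0.10, camera adjusted p = 3.26e-05, and adjusted p = 0.124 with an estimated correlation), including CD2 (-0.39, adjusted p = 0.001). B cell markers had 3 of 12 lower and 0 higher (5 and 1 adjusted over the list alone; median -0.16, camera adjusted p = 0.012, and adjusted p = 0.124 with an estimated correlation), including MS4A1 (-0.31). Chaperones (median 0.14, 1 of 15 higher, adjusted p = 0.002), ribosome biogenesis (0.08, none called, 0.013), sterol synthesis (-0.13, 1 of 16 lower, 4 adjusted over the list alone, 0.005) and glycolysis (0.09, none called, 1 higher adjusted over the list alone, 8.88e-04) had adjusted p = 0.265, adjusted p = 0.153, adjusted p = 0.121 and adjusted p = 0.260 with an estimated correlation.

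The other 13 lists had camera adjusted p from 0.095 for platelet and erythroid markers to 0.964 for APOBEC3. The stress response list had a median of -0.01 (adjusted p = 0.723). The platelet chemokine gene PPBP was 1.76-fold higher with doxorubicin (log2 0.81 ± 0.16, adjusted p = 0.006, 6 of 6 arrays), and CD14 was lower in 5 of 6 arrays (-0.54, adjusted p = 0.035), a call lost when any of 7 arrays was left out. Centring turned the sign of the medians for apoptosis (0.00 as deposited), Toll-like receptors (0.04) and T cell activation (0.00). Test and median differed in sign for anti-apoptosis (median -0.05, mean 0.01). Among single genes, CYP4F3 was 9.27-fold lower with doxorubicin (log2 -3.21 ± 0.45, adjusted p = 3.21e-04), where its signal of 57.3 lay below the array medians, and the metallothionein gene MT1M was 1.86-fold lower (log2 -0.89 ± 0.14, adjusted p = 9.56e-04). ERRFI1, a feedback inhibitor of EGF receptor signalling, was 1.69-fold higher (log2 0.76 ± 0.11, adjusted p = 3.21e-04). In each gene named so far as differing between the drugs, all 6 doxorubicin arrays lay on 1 side of their donor's nutlin-3 mean. The exception was CD14, with 5 of 6.

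The drugs differed in 223 of 12448 genes, 98 higher and 125 lower with doxorubicin, of which 3 were higher and 4 lower at least 2-fold. Of the 10 lists called, 3 held with an estimated correlation: p53 targets (adjusted p = 0.026), G1/S (0.011) and Fanconi and homologous recombination (0.004). The count was 24 in donor A alone and 216 in donor B alone, and it was 129 with arrays centred on their medians, 20 higher and 109 lower, and 129 with variance moderation without a trend. It was 123, 132 and 139 without nutlin-3 replicate 1, nutlin-3 replicate 3 and doxorubicin replicate 1 of donor B.

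Both drugs called 196 genes in the same direction, 129 up and 67 down, and 0 in opposite directions. These were 67.2% of the genes that rose and 44.7% of those that fell with doxorubicin, where 6 and 4 shared genes would be expected by independence. Because both contrasts use the same DMSO arrays, the overlap was counted again with 3 DMSO arrays of its own for each drug. Over 18 such divisions it was 84 to 106 (mean 95.7). These fits with fewer control arrays called a mean of 176.5 genes for doxorubicin and 374.5 for nutlin-3. Simulations with no drug effect, in which both drugs shared the DMSO arrays, gave an overlap of 0.0. Such simulations leave few genes to call, so they cannot show how far shared controls raise the overlap. Across genes, which are not independent replicates, the log2 fold changes of the drugs correlated with r = 0.60, against 0.50 in simulations with no effect and 0.17 to 0.24 with separate controls. The overlap was 44 in donor B alone, 127 with arrays centred on their medians and 114 without _x_at and _s_at probe sets.

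**Figure D3:**
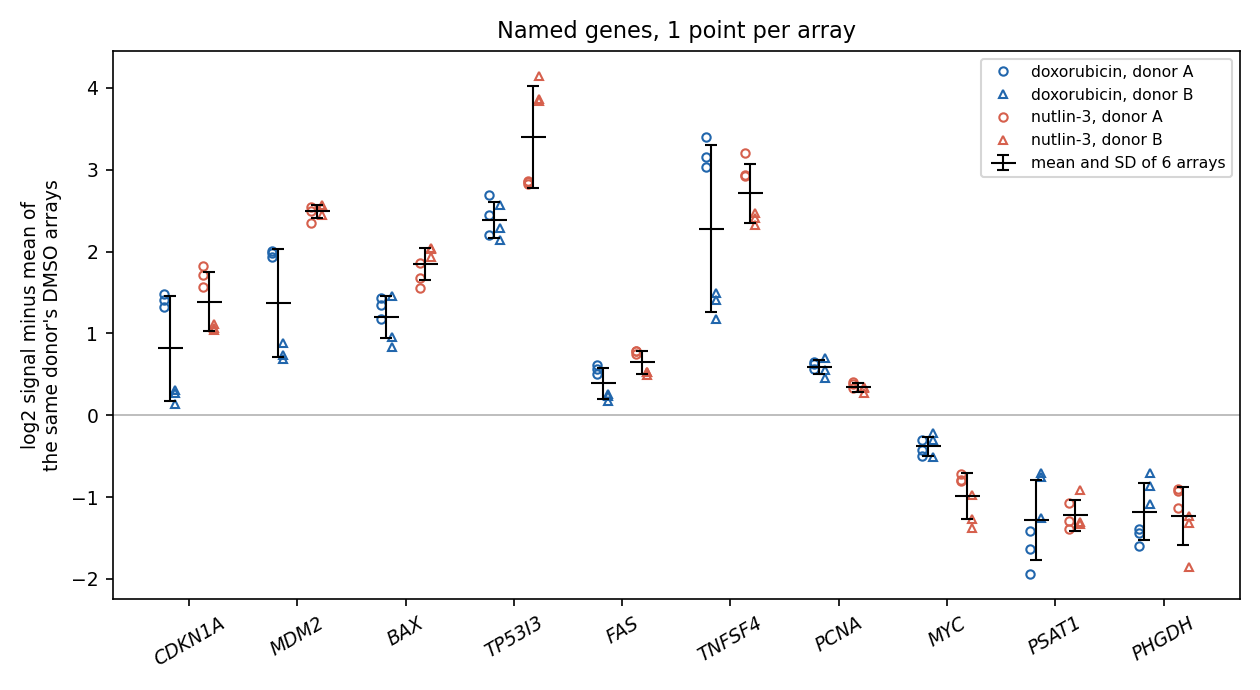
Log2 signal of 10 named genes minus the mean of the same donor's DMSO arrays (vertical axis), 1 point per array, doxorubicin in blue and nutlin-3 in red, donor A as circles and donor B as triangles, with the mean and SD of 6 arrays. MDM2 arrays span 0.69 to 2.01 with doxorubicin and 2.35 to 2.57 with nutlin-3, and those of CDKN1A span 0.14 to 1.48 and 1.04 to 1.83.

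The labels give 2 donors, so the donors' responses to each drug were compared. The p53 targets rose more with doxorubicin in donor A than in donor B. MDM2 had a log2 fold change of 1.97 in donor A and 0.77 in donor B (difference 1.20, adjusted p = 1.00e-04), and CDKN1A of 1.40 and 0.24 (difference 1.16, adjusted p = 0.003). RRM2B differed by 1.22 (adjusted p = 0.007) and TNFSF4, at 3.20 and 1.36, by 1.84 (adjusted p = 1.30e-04). With nutlin-3 the MDM2 values were 2.46 and 2.53.

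In the p53 list, 9 of 45 members responded more to doxorubicin in donor A and 0 in donor B (18 adjusted over the list alone; median difference 0.35, camera adjusted p = 3.05e-20, and 3.79e-05 with an estimated correlation). For nutlin-3 the median difference of the list was -0.06. Of 8 lists called as differing between donors with doxorubicin and 5 with nutlin-3, 1 and 0 held with an estimated correlation. With nutlin-3, G1/S genes differed by a median of 0.25 (0 called, 9 adjusted over the list alone; camera adjusted p = 1.02e-11, and adjusted p = 0.080 with an estimated correlation). The nucleotide metabolism gene DUT had log2 fold changes of 0.12 and -0.55 with nutlin-3 (difference 0.67, adjusted p = 0.001). Centring on the array median moved the median difference of all genes for doxorubicin from 0.01 to -0.13 and that of the p53 list from 0.35 to 0.21, with 1 of its members called in place of 9; centring shifts all genes of an array alike, so the list stood 0.34 above the median of all genes either way.

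For doxorubicin, 21 of 12448 genes differed between donors, all 21 with the higher log2 fold change in donor A, and for nutlin-3, 1 gene did. At an unadjusted p under 0.05 there were 1235 and 808 genes. The difference doxorubicin minus nutlin-3 differed between donors in 83 genes, 38 higher and 45 lower in donor A. With centring the counts were 2 for doxorubicin and 0 for nutlin-3, and it ended the calls of RRM2B (adjusted p = 0.080), CDKN1A (0.053) and DUT (0.369); the MDM2 call ended with the mean of its probe sets (0.321) and without _x_at and _s_at probe sets (0.338). Variance moderation without a trend also ended the calls of RRM2B (adjusted p = 0.083), CDKN1A (0.058) and DUT (0.086), and leaving out _x_at and _s_at probe sets that of DUT (0.907). The doxorubicin count was 9 without doxorubicin replicate 1 of donor A and 12 without doxorubicin replicate 1 of donor B.

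**Figure D4:**
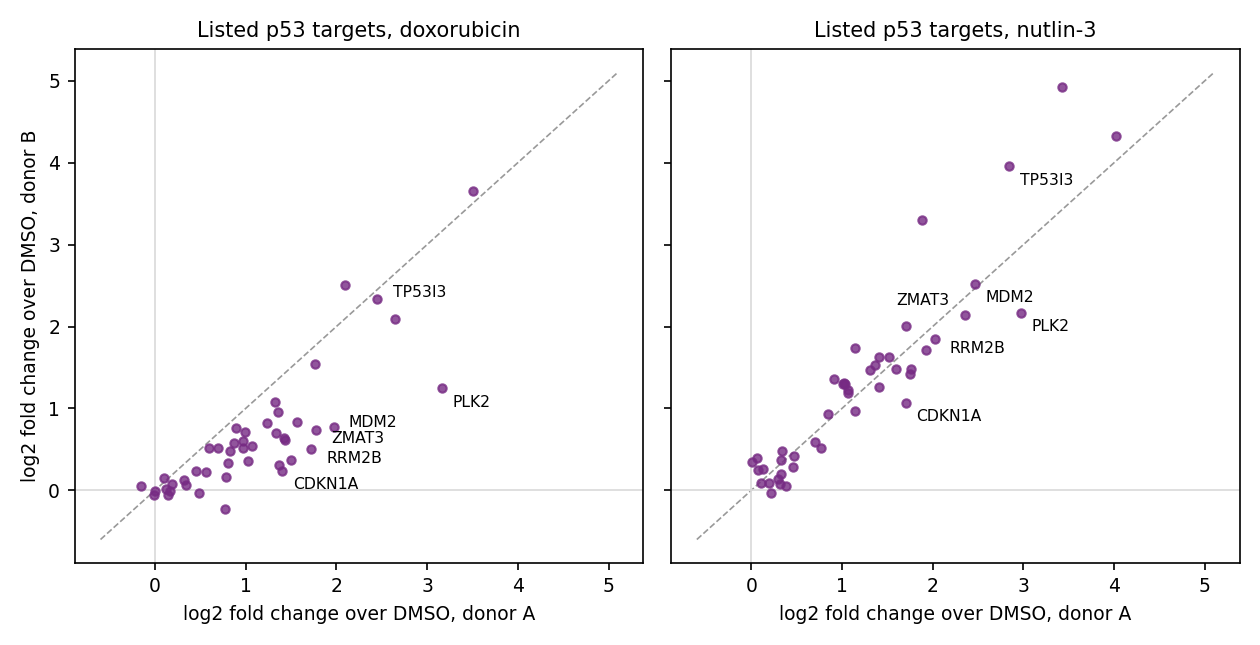
Log2 fold change over DMSO of each of the 45 measured p53 targets in donor A (horizontal axis) and donor B (vertical axis), for doxorubicin on the left and nutlin-3 on the right, with a dashed line of equal change. With doxorubicin 41 of 45 genes lie below the line, and with nutlin-3 21 of 45 do.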

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

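Among the tests here, those for more cells that do not respond and for weaker exposure in donor B, and all camera tests of differences between donors, were chosen only after the result was seen.

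The donors' responses to doxorubicin differed in 21 genes by the interaction test, and those to nutlin-3 in 1 gene, DUT. For doxorubicin, 1 of 100 splits of the arrays, the real one, gave as many, and the highest count among the other splits was 7. This argues against a chance division of these arrays. It cannot exclude chance between cultures or donors. There were 2 donors, the replicates may not be separate cultures, and the other splits mixed arrays of both donors. For nutlin-3 chance cannot be excluded: 8 of 100 splits, the real one included, gave as many genes. The highest of them gave 35, several times the real count. That may reflect a structure of the samples, but none was identified and the cause was not tested. For the drug counts a chance division of these arrays is also argued against, with the same limit on cultures and donors. Only 1 of 100 splits, the real one, gave as many genes. The counts were 342 against a highest other count of 41 for doxorubicin, 656 against 8 for nutlin-3 and 223 against 4 between the drugs. The largest donor differences (donor A minus donor B, log2) with doxorubicin were 2.53 for CXCR2, 1.84 for TNFSF4, 1.22 for RRM2B, 1.20 for MDM2 and 1.16 for CDKN1A, and with nutlin-3 0.67 for DUT. The CXCR2 call (adjusted p = 0.047) was lost when any of 15 arrays was left out.

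The p53 targets as a list also rose more with doxorubicin in donor A than in donor B, by a median of 0.35. In the difference doxorubicin minus nutlin-3, donor A minus donor B was 0.53 for p53 targets, -0.24 for G1/S genes and -0.38 for G2/M genes, each called with the preset and with the estimated correlation (adjusted p = 4.00e-05, 0.046 and 0.029 with an estimated correlation). Probe sets with no gene or several genes stood outside the comparisons; of 5606 tested, doxorubicin changed 25 and nutlin-3 changed 81.

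The first pattern weighed is the weaker rise of p53 targets with doxorubicin in donor B, whose median was 0.53 times that in donor A (95% bootstrap interval over genes 0.31 to 0.62). This interval and the next resample genes, which are not independent, and hold no spread between arrays or donors. More cells in donor B that respond to neither drug would lower the nutlin-3 response too, by the same ratio under the prediction made. That ratio was 1.19 (0.76 to 1.30), which argues against such cells as the whole cause. Cells that respond to nutlin-3 but not to doxorubicin would leave the nutlin-3 ratio unchanged. The test cannot speak to them, and they stay open. A single deviating array and the scaling are also argued against as the whole cause, since the lowest median difference with an array left out was 0.27 and quantile normalization gave 0.36 (centring gave 0.21, a shift of all genes alike that leaves the list 0.34 above their median). A candidate explanation is a weaker doxorubicin exposure of the cells of donor B: 75.9% of the 311 called genes outside the list changed less in donor B (exact binomial p = 1.51e-20, with genes not independent), against 42.3% of 624 with nutlin-3. A difference between the donors in how cells respond to DNA damage could also give smaller changes in donor B. The share therefore does not favour exposure over such a difference, which stays open and was not tested.

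The second pattern is the higher level of G1/S genes with doxorubicin than with nutlin-3, a median of 0.29. A single deviating array is argued against, since the lowest median with a drug array left out was 0.24. The median was 0.14 in donor A and 0.40 in donor B, so the pattern may come mainly from donor B, and the donor difference passed its own test (above). A difference between the drugs in how far cells had left the cycle stays open and was not tested.

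The third pattern is the fall of ATF4 and stress response genes with both drugs, by medians of -0.46 with doxorubicin and -0.40 with nutlin-3. Chance values of a few of the shared DMSO arrays are argued against, since the smallest fall over 18 sets of 3 DMSO arrays was -0.35. All sets came from the same 6 DMSO arrays, so a high level common to these arrays cannot be excluded. Scaling is argued against, since quantile normalization gave -0.45 and -0.40, and centring -0.50 and -0.39. The vehicle cannot account for both, as nutlin-3 had the control's vehicle. No biological explanation was tested.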

How the results depend on the processing

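The list tests of donor differences, and the runs for genes of the lists chosen later, were added after the data were seen; other alternatives were planned, and the cause of a change was not tested. With arrays centred on their medians the count was 205 for doxorubicin, 397 for nutlin-3, 129 between the drugs, 127 in the overlap, and 2 and 0 for donor differences (doxorubicin, nutlin-3); 204 of the 342, 396 of the 656 and 121 of the 223 genes were shared, and the upward share between the drugs went from 43.9% to 15.5%. Without _x_at and _s_at probe sets, which leaves fewer genes, the counts were 204, 404, 114 in the overlap, and 13 and 0 for donor differences. Without a trend they were 129 between the drugs and 3 and 0 for donor differences. The mean of a gene's probe sets gave 13 and 2, the 75th percentile filter 32 and 4, and the replicate block 13 for doxorubicin. Donor B alone gave 52 for doxorubicin, 323 for nutlin-3 and 44 in the overlap, and donor A alone 210 for nutlin-3 and 24 between the drugs, with fewer arrays. List calls were 14 for doxorubicin in donor B alone and 6 between the drugs in donor A alone. With an estimated correlation, calls went from 13 to 8 lists for nutlin-3, from 10 to 3 between the drugs, from 8 to 1 for donor differences with doxorubicin and from 5 to 0 with nutlin-3. Fry, which does not compare a list with other genes, called 7 lists for doxorubicin, 12 for nutlin-3 and 7 between the drugs. For donor differences it called 1 list with doxorubicin and 1 with nutlin-3.

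With each array left out in turn the count was 231 to 387 for doxorubicin, 515 to 670 for nutlin-3, 123 to 226 between the drugs, 152 to 204 in the overlap, 9 to 30 for the doxorubicin donor difference (9 without doxorubicin replicate 1 of donor A, 12 without that of donor B) and 1 to 6 for the nutlin-3 one. That last count was 6 without DMSO replicate 3 of donor A, and 2 without DMSO replicate 1 or 2 of either donor, doxorubicin replicate 1 or nutlin-3 replicate 3 of donor B. Of 5871 alternative values for 187 named gene results, 5148 kept direction and call, 718 kept direction only and 5 reversed: BCL11B with doxorubicin (0.01) and APOBEC3G with nutlin-3 (-0.17) with the mean of their probe sets, and COG8 with nutlin-3 (0.75) and between the drugs (-0.16) and FAS between the drugs (0.01) without _x_at and _s_at probe sets. Of the 187, 60 passed under every setting and 47 were lost without at least 1 array. Where named called genes had several probe sets, another stood on the other side of 0 for 5 of 20 with doxorubicin and 5 of 24 with nutlin-3. Signal near background limits dim genes such as SPATA18 and GDF15, with DMSO signals of 7.8 and 12.3.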

Other observations

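The lists in this part were chosen after the values were seen, all 3 tests here with them, and for the TNF superfamily the estimated correlation was added as a criterion after its result. The lists keep genes already seen to change, TNFSF4 and TNFSF8 in the TNF superfamily and MT1M in the metallothioneins. The camera p-values here therefore describe these data and are not independent evidence.

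In the TNF superfamily, 4 ligand genes outside the p53 list rose with both drugs, among them TNFSF8, which the T cell activation list also holds. Of 31 measured ligands and receptors, 4 rose and 1 fell with doxorubicin and 4 rose with nutlin-3. CD70, the ligand of CD27, rose by 1.04 and 1.40 (log2, doxorubicin and nutlin-3), TNFSF9 (4-1BB ligand) rose by 0.83 and 0.80, TNFSF4 by 2.28 and 2.71 and TNFSF8 by 1.08 and 1.44. The receptor gene TNFRSF13B was the one that fell, by 0.75 with doxorubicin. That call was lost when any of 8 arrays was left out, as were those of TNFSF9 for 8 arrays with doxorubicin and 7 with nutlin-3. As a set, the camera adjusted p was 0.008 with doxorubicin and 6.27e-04 with nutlin-3, but with an estimated correlation adjusted p = 0.093 and adjusted p = 0.053, so whether the family rose as a set stays undecided.

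Cytosolic tRNA synthetase genes outside the stress response list, whose products load amino acids onto tRNA, fell with both drugs. With doxorubicin 7 of 14 fell and 0 rose (median -0.27, camera adjusted p = 2.00e-12, and 0.002 with an estimated correlation). With nutlin-3, 7 fell and 1, RARS1 (0.44), rose (median -0.22, camera adjusted p = 5.46e-07, and 0.024 with an estimated correlation). IARS1 fell by 0.53 with doxorubicin and by 0.44 with nutlin-3, and NARS1 by 0.44 and by 0.32. Metallothionein genes, whose products bind zinc and copper, were lower with doxorubicin than with nutlin-3 in 6 of 8 cases (median -0.37, camera adjusted p = 7.74e-12, and 0.008 with an estimated correlation). The differences were -0.89 for MT1M, -0.50 for MT1E, -0.42 for MT1H, -0.41 for MT1F, -0.32 for MT1X and -0.30 for MT2A; that of MT1X was not called with the mean of its probe sets (adjusted p = 0.066). The probe sets of this family can match several of its members, so the 6 are not independent measurements. The vehicles of the drugs also differed, so this difference holds drug and vehicle together.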
